A study of Mus musculus with 24 samples.

How the data were processed

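Total RNA of the ventromedial hypothalamus (VMH), dissected from 100 µm brain sections, and of 20 mg of brown adipose tissue (BAT) was measured on 24 Affymetrix arrays, per the labels. Mice carrying a conditional deletion of the clock gene Bmal1 directed by Gfap, a gene of astrocytes (labelled cKO), and control mice had eaten standard diet (SD) or high fat diet (HFD) for 16 weeks. Each of the 8 groups of tissue, genotype and diet held 3 arrays. The labels do not state that the arrays of a group came from separate animals, so p-values measure the spread between these arrays, which may be technical.

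The deposited values are log2 signals, 1 column per array, between 2.1167 and 19.932; the highest corresponds to a linear signal of 999952 and acts as a ceiling. Affymetrix Expression Console 1.1.1 and PLIER 2.0 are named per the submitters' processing notes, with no role given. The between-array normalization and the genome build are not given in the sources used here. Array medians lay between 5.482 and 5.572 in VMH and between 4.069 and 4.158 in BAT, so all comparisons were made within a tissue. The number of arrays limits the precision of each value. No pair of arrays was identical.

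Of 72688 features in the table, 6732 were controls. Among the others, 30604 had 1 gene symbol, 2146 had several and 33206 had none in the platform annotation. Symbols were updated for 827 features through a mouse gene table of assembly GRCm38.p6, to which 22818 features matched; that table served only for names and for which genes neighbour each other. Features without a single symbol entered no gene comparison. A feature was tested when its mean over the arrays of a tissue reached the median of that mean over the table (5.5069 in VMH, 4.1275 in BAT), and the brightest feature stood for a gene with several. This left 16211 genes in VMH and 17124 in BAT.

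The deposited values were used without further normalization. limma 3.58.1 in R 4.3.3 fitted group means over the 12 arrays of each tissue, with no block and equal weights, and gave 6 comparisons per tissue: cKO minus control on each diet and averaged over diets, HFD minus SD in each genotype, and the interaction. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Chance alone would put 811 VMH and 856 BAT genes at an unadjusted p under 0.05 in a comparison. The design, the rule for named genes and 40 gene lists were fixed before the data were examined. Named genes were Bmal1 and up to 6 clock genes; the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap between groups; the 4 highest and 4 lowest statistics where fewer than 6 genes passed; and up to 4 members of a list by smallest p. Predicted genes and small RNAs were left out of the rises, falls and statistics by symbol patterns, which do not cover Scarna17, a small RNA of Cajal bodies. The same 4 highest and lowest statistics are also given for the averaged comparison.

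Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with a correlation estimated for the list, which ended all calls, and with fry, which asks whether a list's genes move one way on balance and does not set them against other genes. Values given as mean ± SE for a list have their SE over its genes, which does not measure the spread between arrays. Exact permutation tests of Bmal1 and of BMAL1 targets used all 400 rearrangements of genotype within diet and were two-sided.

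The procedure was tested on simulated data in which 200 genes were changed by 1 or 2, and a list of 20 others by 0.5, in the comparison of genotypes on HFD. In VMH, over 16211 genes, 95% of changes of 1 on the log2 scale and 98% of changes of 2 were recovered, and 9 of 209 calls fell on genes that were neither changed nor in the list. In BAT, over 17124 genes, the shares were 51% and 89%, with 8 such calls among 152. The simulated noise was independent between genes and arrays. The real arrays share structure across genes, with 72.2% of the BAT variance on the first principal component. These shares therefore need not hold for the real data, least of all in BAT.

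Alternatives were quantile normalization, a pseudocount of 16 on the linear scale, no filter, the mean of a gene's features, a trended and robust prior, only the groups compared, array weights, a replicate block, and leaving out each array. Added after seeing the data were the skeletal muscle score as a covariate in BAT, BAT without the 2 arrays of lowest Ucp1, a hypothalamic neuropeptide score as a covariate in VMH, each list call with 1 member past the threshold without that member, and the BAT muscle difference without markers whose 2 highest arrays lay within 0.05.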

Results

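Gene expression was measured in the VMH, a hypothalamic nucleus that regulates energy balance, and in BAT, the thermogenic fat, of control mice and of mice labelled Gfap-Bmal1 cKO, on SD or HFD. The study asked how the clock of astrocytes bears on energy expenditure. Each group held 3 arrays, 24 in all. Arrays of a tissue correlated at 0.992 to 0.997 in VMH and at 0.891 to 0.996 in BAT, and the first principal component held 19.3% and 72.2% of the variance.

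Bmal1 itself (Arntl), the targeted gene and a core transcription factor of the clock, was not lower in the arrays labelled cKO. In VMH its log2 signal was 8.62 ± 0.16 in controls and 9.17 ± 0.21 in cKO arrays on SD, and 8.95 ± 0.23 and 9.19 ± 0.30 on HFD (SD, n = 3). Averaged over diets it was 0.395 higher (95% interval 0.133 to 0.658; exact permutation p = 0.03, where 0.005 is the smallest possible), with a limma adjusted p of 0.243. In BAT the difference was 0.37 (interval -0.161 to 0.9; exact permutation p = 0.155). The deleted part of the gene is not given in the labels, so this feature can check the genotype only if it lies within it. Even then, a deletion directed by Gfap leaves the transcripts of other cells in a bulk sample. The samples are therefore called arrays labelled cKO, or cKO arrays for short, and each direction rests on that label.

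On SD, 41 VMH genes rose and 3 fell in the arrays labelled cKO. The largest rise was of Fabp7, a fatty acid binding protein of astrocytes and neural progenitors, from 12.42 ± 0.43 to 16.13 ± 0.10 (SD, n = 3), a log2 change of 3.71 ± 0.33 (SE). Cdkn1a, a cell cycle inhibitor, rose by 2.28 ± 0.16, the membrane metalloprotease gene Mmp14 by 2.04 ± 0.13, Id2, an inhibitor of helix-loop-helix factors, by 1.87 ± 0.14, and Plat, tissue plasminogen activator, by 1.79 ± 0.15. Egfl6 (1.37), Npas2 (1.1) and Emp2 (1.04) also rose. Etnppl, a phospholyase of astrocytes, fell by 2.07 on the log2 scale and Prex2 by 1.21.

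The limma adjusted p was 0.000153 for Mmp14 and 0.000602 for Fabp7, and all 44 genes had groups that did not overlap, which 9.93% of all genes also showed, against 10% by chance. The count fell to 22 without cKO array 2, to 24 without cKO array 3 and to 29 without control array 2. The split by direction also moved: it was 38 higher and 13 lower without control array 1, and 53 higher and 9 lower with array weights. Of the fits that left out 1 array, Npas2 and Prex2 passed only in that without control array 1 (otherwise adjusted p 0.0573 to 0.078 and 0.119 to 0.196). Egfl6 lost its call without control array 2 or 3 or cKO array 1 or 2, with adjusted p from 0.0656 to 0.0933, and Emp2 without control array 1 or 2 or cKO array 2 or 3 (0.0554 to 0.0671). With only these 6 arrays in the fit, 10 genes passed, 8 higher and 2 lower.

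**Figure D1:**
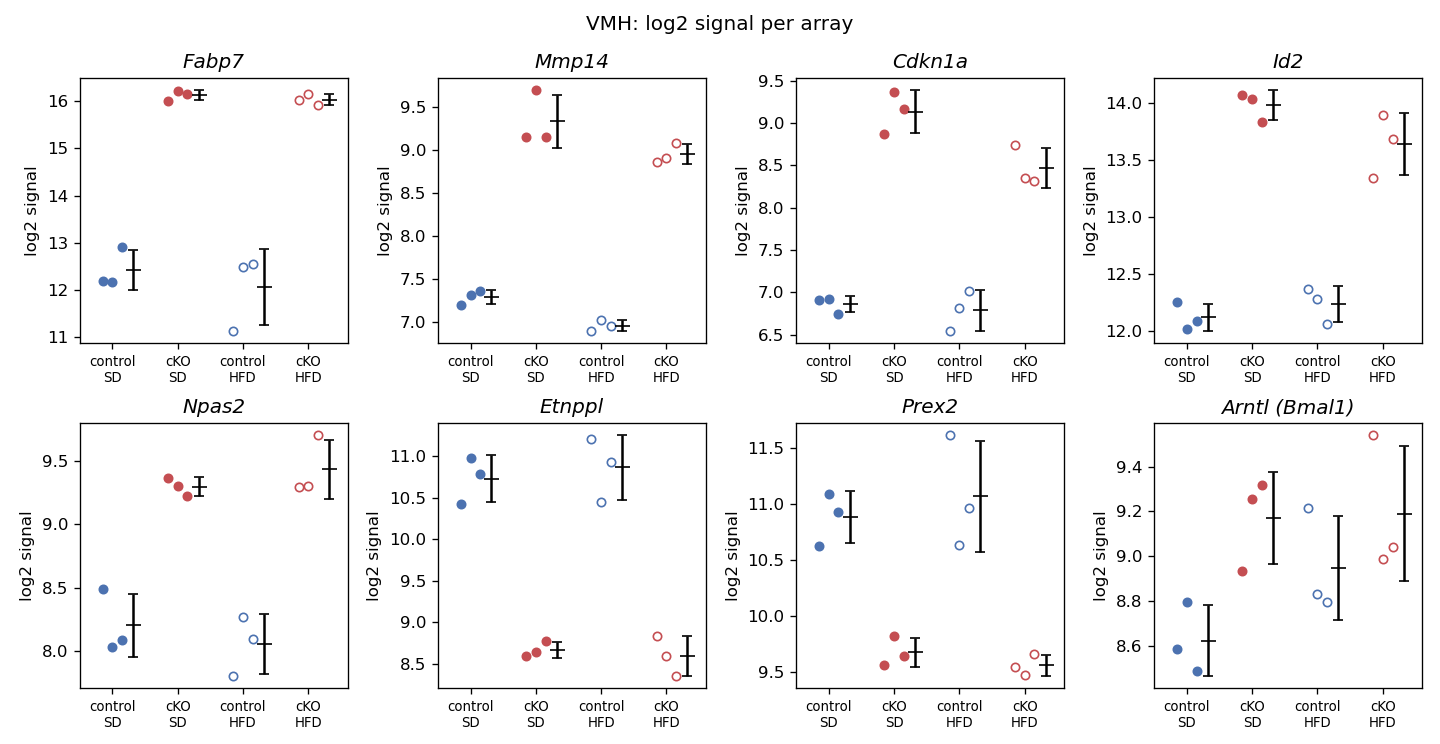
Log2 signal (vertical axis) of 8 VMH genes on each array, by genotype and diet (horizontal axis), control in blue and cKO in red, SD filled and HFD open; bars give mean and SD of 3 arrays. Fabp7 stood at 16.13 and 16.03 on average in the cKO groups against 12.42 and 12.05 in controls, and Arntl was not lower in the cKO groups.

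On HFD, 39 VMH genes rose and 10 fell in the arrays labelled cKO. Fabp7 rose by 3.98 ± 0.33 (SE), Mmp14 by 1.99 ± 0.13, Egfl6 by 1.84 ± 0.20, Plat by 1.69 ± 0.15, Cdkn1a by 1.68 ± 0.16, Id2 by 1.41 ± 0.14 and Npas2 by 1.38 ± 0.16. Ncan, which encodes the proteoglycan neurocan, rose by 1.01. Etnppl fell by 2.27 on the log2 scale, Prex2 by 1.51 and the cadherin gene Cdh19 by 1.45; Phyhd1 (-0.512), Cyp4f14 (-0.461) and Zkscan2 (-0.376) fell less.

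Between the diets, 34 genes passed in both with the same sign, against 0.1 expected of independent lists of 44 and 49 genes. Both comparisons come from 1 fit and share each gene's estimate of the spread, so 0.1 is not a strict level of chance. Across genes the genotype effects on the 2 diets correlated at a Pearson r of 0.323 (Spearman 0.192); genes are not independent replicates, and 0 of 100 rearrangements reached that value, the highest being 0.304. Limma's count on HFD fell to 31 without control array 3 or cKO array 3 and to 32 without control array 1 or cKO array 2, and reached 121 with array weights (92 higher and 29 lower). The falls numbered 3 without cKO array 3 and 4 without control array 1 or 3 or cKO array 2. Phyhd1 and Cyp4f14 lost their call without any single array (adjusted p 0.0524 to 0.181), Zkscan2 without any but cKO array 2 (0.0736 to 0.124), Cdh19 without control array 3 or any cKO array (0.0583 to 0.1), and Prex2 without cKO array 2 (0.0612). The adjusted p of the calls named was 0.000195 for Mmp14 and 0.000565 for Fabp7 and Etnppl; all 49 genes had groups that did not overlap, as did 20.1% of all genes, against 10% by chance.

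Among 19 measured members of the core clock list, 1 rose (Npas2, a paralog of Clock) and 18 did not pass on SD, with 1 also when adjusted over the list alone. On HFD Per3 differed by -0.496 ± 0.119 (SE, limma adjusted p = 0.159) and Clock by 0.216 ± 0.055 (adjusted p = 0.187). Neither passed the threshold over all genes, though both passed when adjusted over the list alone. Cry1 and Cry2 differed by 0.154 and 0.2 on SD.

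In VMH on SD, genes of oligodendrocytes, the myelinating cells, averaged -0.57 ± 0.075 in arrays labelled cKO, with 16 of 17 members negative and 0 calls by limma, also when adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.931 with an estimated correlation). This mean depended on single arrays: it was -0.206 without control array 3, -0.313 without cKO array 1 and -0.916 without control array 1. The mean signal of the list was 9.65, 10.31 and 11.07 on control arrays 1 to 3, and 9.26, 10.22 and 9.85 on cKO arrays 1 to 3. Ermn stood at -1.15, Fa2h at -0.792, Gjc3 at -0.698 and Olig2 at -0.288. Of another glial type, Gfap, the astrocyte gene that directs the deletion, had a log2 signal of 11.45 ± 1.07 in controls and 12.98 ± 0.25 in cKO arrays (SD, n = 3), a difference of 1.53 ± 0.448 (SE; limma adjusted p = 0.48). Astrocyte markers averaged 0.145 over 22 genes, with 0 calls by limma and 3 higher over the list alone (camera adjusted p = 0.196). Glucocorticoid responsive genes averaged 0.307 over 15 genes, of which 1 rose (Cdkn1a) and 2 when adjusted over the list alone (camera adjusted p = 0.00282; adjusted p = 0.931 with an estimated correlation). Without Cdkn1a their mean was 0.167 (camera adjusted p = 0.0476). Without control array 1 it was 0.222 and the call ended (0.208). Mertk, a phagocytic receptor kinase, was at 0.357 and Zbtb16 at 0.376.

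Interferon response genes averaged 0.193 over 12 genes (Ddx58 0.340, Ifit1 0.516), with 0 calls by limma and 1 when adjusted over the list alone. Pituitary, choroid plexus and meninges markers averaged 0.371 over 13 genes (Clic6 0.370, Kcnj13 1.14), with 0 calls and 1 over the list alone, extracellular matrix genes 0.399 over 10 (1 rose, Mmp14; Fn1 at 0.663), and proteasome genes 0.0887 over 24 (Psma1 0.241), with 0 calls. Each of these 4 lists had a camera adjusted p of 0.0159 and an adjusted p = 0.931 with an estimated correlation. Mmp14 supplied much of the matrix mean, which was 0.217 over the other members, where the call ended (adjusted p = 0.239). Without control array 1 all 4 calls ended, with means of 0.113, 0.185, 0.28 and 0.0663 in that order and camera adjusted p of 0.274 for the first and 0.208 for the others. Without cKO array 1 the calls of the first 3 ended (0.187, 0.331 and 0.401, with adjusted p 0.0663, 0.157 and 0.0725). The interferon call also ended without cKO array 3 (0.145, adjusted p = 0.222), the pituitary and matrix calls without control array 2 (0.335 and 0.362, with adjusted p 0.136 for both), and the proteasome call without cKO array 2 (0.0446, adjusted p = 0.358) and with array weights (0.0755, adjusted p = 0.0643), while the pituitary mean was 0.592 without control array 3. The number of lists past the threshold, 6, was 1 without control array 1 and 11 without control array 3.

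On HFD oligodendrocyte genes averaged -0.378 over 17 genes, with 14 negative and 0 calls by limma, but Olig2, a lineage transcription factor, stood at +0.502 (1 call over the list alone; camera adjusted p = 0.0279; adjusted p = 0.987 with an estimated correlation). That list call ended without control array 3 (-0.301, adjusted p = 0.0921) or cKO array 2 (-0.319, adjusted p = 0.109). Gfap stood at 11.33 ± 0.382 in controls and 12.42 ± 0.519 in cKO arrays (SD, n = 3; limma adjusted p = 0.397), and astrocyte markers averaged 0.0936 over 22 genes, with 0 calls and 1 lower over the list alone (camera adjusted p = 0.915). Oxidative phosphorylation genes averaged 0.116 over 38, with 36 positive and 0 calls; ribosomal protein genes averaged 0.157 over 14, all positive. General neuron markers averaged 0.135 over 20, of which 1 rose, Stmn2 at 0.891 ± 0.073 (SE), and 2 over the list alone; Tubb3 stood at 0.445. These 3 lists each had a camera adjusted p of 0.0289 and an adjusted p = 0.987 with an estimated correlation. Stmn2 lies among the chromosome 3 neighbours described with the averaged comparison, and without it the neuron list averaged 0.095 and its call ended (adjusted p = 0.154). All 3 calls ended after quantile normalization (0.155, 0.213 and 0.136, with adjusted p 0.0663, 0.0657 and 0.441). The oxidative phosphorylation call ended without control array 2 (0.105, adjusted p = 0.174) or cKO array 1 (0.104, adjusted p = 0.176), the ribosomal call without control array 2 (0.124, adjusted p = 0.234) or cKO array 2 (0.105, adjusted p = 0.273), with only these groups (0.157, adjusted p = 0.0652) and with array weights (0.143, adjusted p = 0.123), and the neuron call without control array 3 (0.104, adjusted p = 0.201), cKO array 1 (0.147, adjusted p = 0.0501) or cKO array 3 (0.0989, adjusted p = 0.166) and with only these groups (0.135, adjusted p = 0.112).

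Averaged over diets, 90 VMH genes rose and 17 fell, with Mmp14 (2.02 ± 0.093, SE), Cdkn1a (1.98), Id2 (1.64) and Zc2hc1a (0.929) at the highest statistics and Etnppl (-2.17), Prex2 (-1.36), Cdh19 (-1.32) and Gpld1 (-0.927) at the lowest. Without control SD array 1 the split was 93 higher and 37 lower, without cKO HFD array 3 it was 69 and 11, and with array weights 155 and 53. Of these 107 genes 19 lie on chromosome 3 in the GRCm38.p6 gene table, and 12 of the 107 are neighbours from Pex2 to Snx16, a region singled out after its values were seen. There the 14 named genes of the highest window of 20 neighbours were all positive, with a median of 0.691 (quartiles 0.555 to 0.792); Stmn2, Fabp5 and Impa1 rose by 0.796, 0.717 and 0.75. Beyond Snx16, Ralyl (-0.0434 ± 0.045) and Lrrcc1 (-0.0692 ± 0.044) did not pass. Of the lists, oligodendrocyte genes averaged -0.474, oxidative phosphorylation 0.095, ribosomal proteins 0.115 and proteasome genes 0.0856 (camera adjusted p = 1.93e-07, 0.0121, 0.0225 and 0.0225), each with an adjusted p = 0.929 with an estimated correlation. The oligodendrocyte mean was -0.292 without control SD array 3. Astrocyte markers averaged 0.119 over 22 (camera adjusted p = 0.438), with 6 higher and 2 lower over the list alone and 1 rise over all genes, of the water channel gene Aqp4 by 0.475 (limma adjusted p = 0.0479). Aqp4 lost its call without any single array but control SD arrays 1 and 3 (adjusted p 0.0559 to 0.14), without the filter (0.0758) and with the neuropeptide score as a covariate (0.0845). Gfap differed by 1.31 ± 0.317 (SE; adjusted p = 0.126), and passed without control SD array 3 (1.57, adjusted p = 0.0226) and with array weights (1.19, adjusted p = 0.0422). The other 3 calls ended without control SD array 1 (0.0695, 0.0959 and 0.0744, with adjusted p 0.119 for each) and without cKO SD array 2 (0.0661, 0.084 and 0.0635, with adjusted p 0.0866 for each), the ribosomal and proteasome calls also without control HFD array 2 (0.0988 and 0.068, with adjusted p 0.13 and 0.166) or cKO HFD array 2 (0.0892 and 0.0702, with adjusted p 0.0959 for both) and with array weights (0.0931 and 0.0734, with adjusted p 0.127 and 0.0878), and the proteasome call without cKO HFD array 1 (0.0845, adjusted p = 0.0508) and after quantile normalization (0.0998, adjusted p = 0.088). The 4 lists were 1 without control SD array 1 or cKO SD array 2 and 2 without cKO HFD array 2, against 7 without cKO HFD array 1 and 9 without control SD array 3. In BAT 15 of the 17 named genes of that region were positive, with a median of 0.461 and 0 past the threshold in limma (1495 of all BAT genes at an unadjusted p under 0.05). The negative ones were Fabp5 (-0.331 ± 0.300, SE) and Hey1 (-0.525 ± 0.343). Of the other genes named for VMH, Stmn2 stood at 0.0863 ± 0.0784 and Impa1 at 0.757 ± 0.231.

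**Figure D2:**
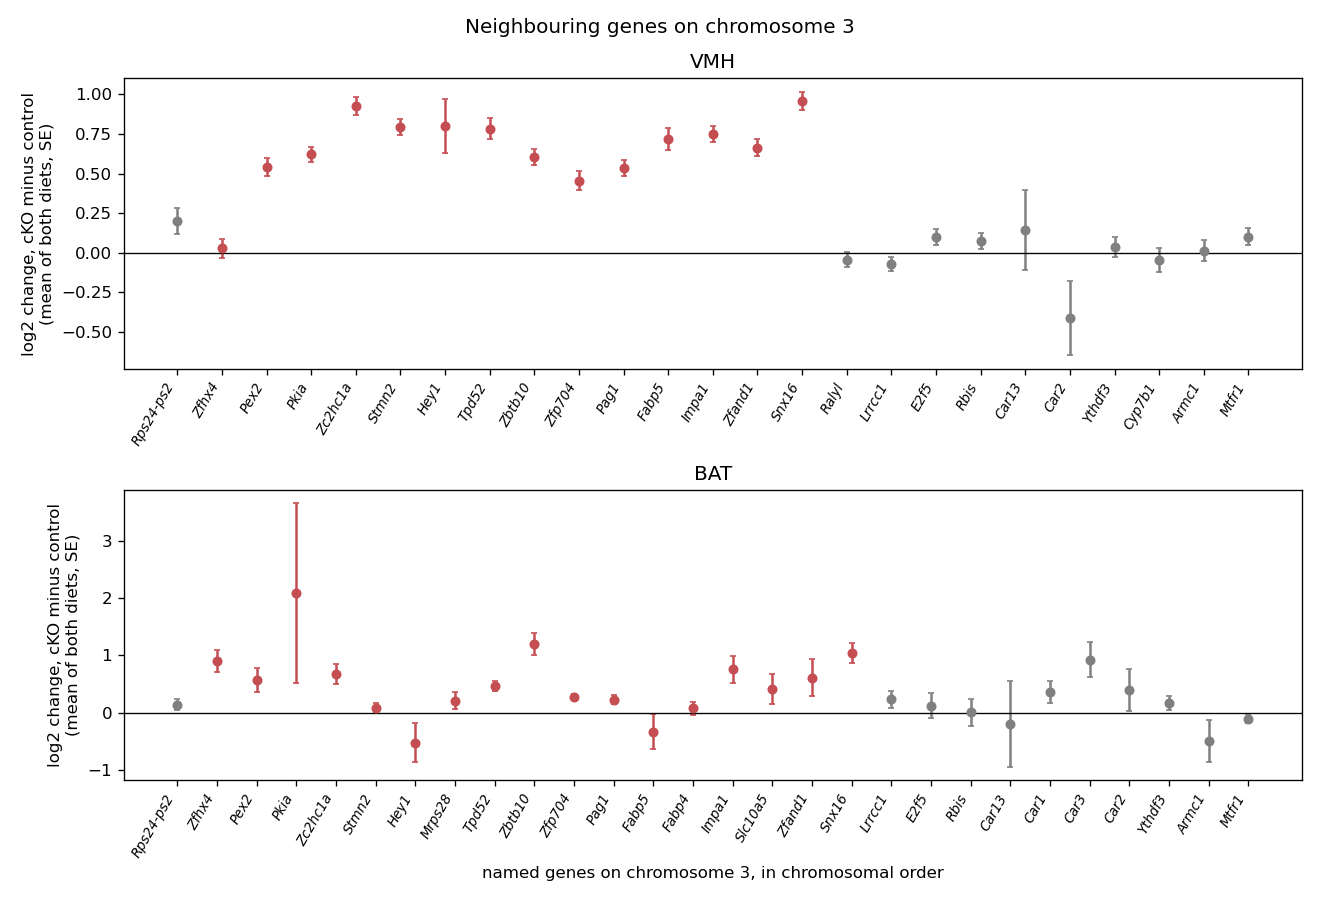
Log2 change, cKO minus control averaged over diets with its SE (vertical axis), of named genes in chromosomal order on chromosome 3 (horizontal axis), in VMH and BAT; red marks the window chosen from the VMH values. In VMH 14 of 14 red genes lay above 0, with Snx16 at 0.959.

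The interaction of genotype and diet gave 0 genes by limma in VMH, with 911 at an unadjusted p under 0.05. Klhl34 (0.763), Olig2 (0.791), Avpr1a (0.704) and Mrm3 (0.356) had the highest statistics and Zkscan2 (-0.449), Fam214a (-0.554), Mertk (-0.584) and Mysm1 (-0.459) the lowest, each with an adjusted p of 0.856. A difference of genotype effects between the diets was therefore not shown for any gene.

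HFD had little measured effect on single VMH genes. In controls limma called 0 genes (1377 at an unadjusted p under 0.05). Map3k5 stood at 0.5, Gpr83 at 0.468, Rab3gap1 at 0.337 and Hprt at 0.359, against Rps12-ps7 at -0.323, Xxylt1 at -0.240, Slc52a3 at -0.238 and Cdca4 at -0.366, with adjusted p from 0.213 to 0.346. Of 24 markers of VMH neurons 19 were positive, with a mean of 0.198, 0 calls and 1 over the list alone (camera adjusted p = 0.00402; adjusted p = 0.987 with an estimated correlation). That call ended without SD array 2 (0.175, adjusted p = 0.107) or HFD array 2 (0.132, adjusted p = 0.342). The score of other hypothalamic neuropeptides was 9.48, 9.51 and 9.02 on control SD arrays 1 to 3. On control HFD arrays 1 to 3 it was 9.40, 8.80 and 8.61. With this score as a covariate the VMH neuron mean was 0.18 (camera adjusted p = 0.0223). Adcyap1, which encodes the neuropeptide PACAP, stood at 0.859 ± 0.179 (SE; adjusted p = 0.346). All 17 oligodendrocyte markers were negative, with a mean of -0.368 and 0 calls (camera adjusted p = 0.000373; adjusted p = 0.987 with an estimated correlation). This rested on control SD array 3, with the highest signal of the list (11.07): without it the mean was -0.00396 and the adjusted p 0.78, and without control SD array 1 the mean was -0.714. The lists past the threshold numbered 2, and 6 without control SD array 1. Diet effects in the 2 genotypes correlated at 0.239 across VMH genes (Spearman 0.209; 4 of 100 rearrangements were as high), and at 0.122 without control SD array 3.

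In arrays labelled cKO, HFD raised 1 VMH gene, Snord58b, a small nucleolar RNA outside the rule for named genes and named after its value was seen, by 0.872 ± 0.073 (SE; limma adjusted p = 0.0022; 1549 genes at an unadjusted p under 0.05). The count was 2 without SD array 3 or HFD array 1, 3 without SD array 2, 20 with array weights and 0 with only these groups in the fit. Slc39a10 (0.408), Cited1 (0.532), Klhl34 (0.586) and Scarna17 (0.650), a small RNA that the symbol patterns of the rule do not cover, had the next statistics, against Flna (-0.312), Mertk (-0.509), Zkscan2 (-0.315) and Atp13a5 (-0.520).

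In these cKO arrays on HFD, unfolded protein response genes averaged 0.156 over 34 (Creld2 0.622, Calr 0.503), with 0 calls by limma, and chaperones 0.170 over 21 (Hsph1 0.569, Stip1 0.551), with 0 calls and 2 over the list alone. Their camera adjusted p was 0.00261 and 0.00307, and each had an adjusted p = 0.578 with an estimated correlation. The first call ended without HFD array 2 (0.1, adjusted p = 0.0661). Glucocorticoid responsive genes averaged -0.253 over 15 with 0 calls and 4 lower over the list alone (Zbtb16 -0.852, Cdkn1a -0.664, Sult1a1 -0.525; camera adjusted p = 5.39e-06; adjusted p = 0.502 with an estimated correlation). Markers of VMH neurons averaged 0.224 and of neurons in general 0.138 (camera adjusted p = 0.000969 and 0.000279), each with an adjusted p = 0.502 with an estimated correlation. The call of neurons in general ended after quantile normalization (0.0875, adjusted p = 0.097). The 10 lists past the threshold were 6 without HFD array 1.

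BAT arrays differed in skeletal muscle transcripts. The mean log2 signal of 24 muscle markers was 13.1 ± 6.38 in controls and 15.9 ± 1.53 in cKO arrays on SD, and 7.16 ± 1.72 and 9.33 ± 3.32 on HFD (SD, n = 3). Of these markers 1 reached the ceiling and 8 had their 2 highest arrays within 0.05 of each other, so differences over the list can be understated. Ucp1, the uncoupling protein of brown adipocytes, was at the ceiling on 9 arrays, and at 8.87 on control SD array 1, 16.3 on cKO SD array 2 and 19.31 on cKO SD array 3. These differences accompany each BAT gene group described here.

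**Figure D3:**
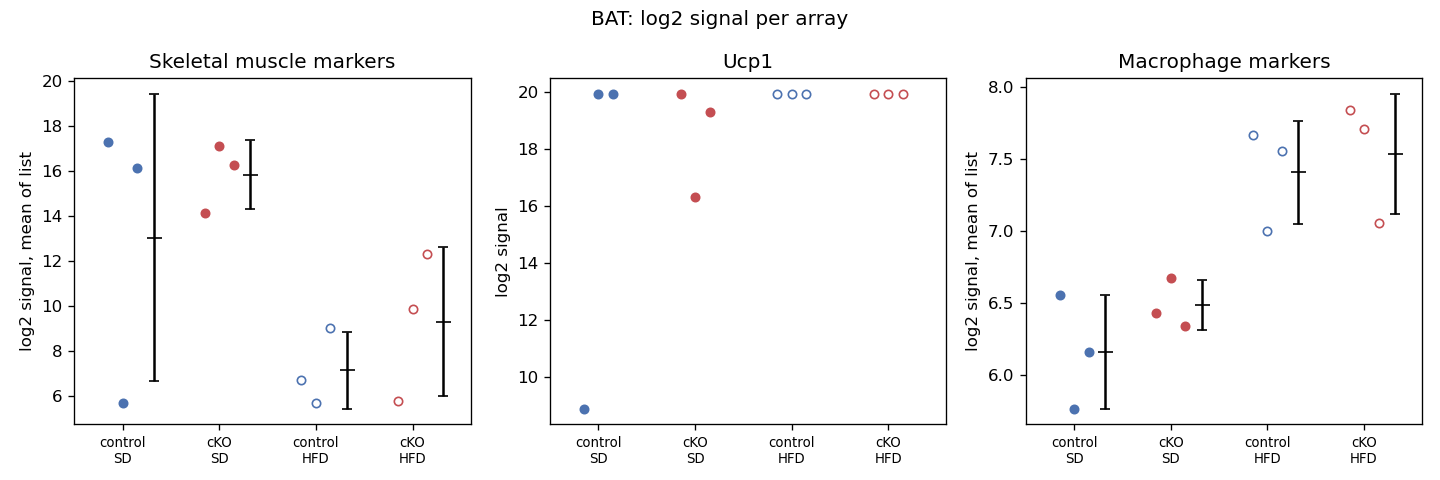
Log2 signal (vertical axes) on each BAT array by genotype and diet (horizontal axis), as the mean of the skeletal muscle list, Ucp1, and the mean of the macrophage list; bars give mean and SD of 3 arrays and are left out for Ucp1, which reached the ceiling of the values. Muscle signal averaged 13.1 and 15.9 on SD and 7.16 and 9.33 on HFD.

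In BAT of controls, HFD raised 107 genes and lowered 25. Mmp12, the macrophage elastase, rose by 3.81 ± 0.55 (SE) and Ctss, a lysosomal protease, by 3.65 ± 0.58. Cd68 rose by 2.85 ± 0.42 and Mpeg1 by 2.82 ± 0.41. The leukocyte receptors Lilrb4a and Lilr4b rose by 3.43 and 2.78, the calcium channel gene Ryr2 by 2.46 and the endothelial gene Eng by 2.45. Irs1, an adaptor of the insulin receptor, fell by 2.09 on the log2 scale. The carboxylesterase Ces1f (-1.5), Tob1 (-1.45), Klhl2 (-1.38), Plaat3 (-1.07), Rsbn1l (-1.03), Lgr4 (-1.01) and Ifit3b (-1.01) also fell. Adjusted p in limma lay between 0.0335 and 0.0496 for the genes named, and all 132 had groups that did not overlap, as did 25.2% of all genes, against 10% by chance.

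This count depended on single arrays. It was 0 without control SD array 3 or HFD array 1, 11 without SD array 1, 20 without HFD array 2, 88 without HFD array 3, and 2716 without SD array 2, the SD array with the lowest muscle signal. It was also 0 with a replicate block, array weights or the muscle score as a covariate, and without the 2 arrays of lowest Ucp1. After quantile normalization it was 80. With only these groups in the fit, 23 genes were higher and 130 lower. With the muscle covariate Mmp12 stood at 4.38, Ctss at 4.05 and Cd68 at 3.22, with adjusted p of 0.0788, 0.112 and 0.0862.

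Of 25 macrophage markers 4 rose (Itgax, 1.37, with Mmp12, Cd68 and Ctss) and 14 over the list alone, with a mean of 1.24 (camera adjusted p = 1.4e-07; adjusted p = 0.495 with an estimated correlation). Endothelial markers averaged 0.691 over 21, of which 3 rose (Eng, Pecam1 1.62, Cldn5 1.58) and 13 over the list alone (camera adjusted p = 0.000852; adjusted p = 0.495 with an estimated correlation). Cell cycle genes averaged 0.507 over 16, with 1 rise, Mki67 by 1.99, and 12 over the list alone (camera adjusted p = 1.06e-05; adjusted p = 0.495 with an estimated correlation). The heme oxygenase gene Hmox1 rose by 2.15 and the chaperone gene Creld2 by 0.746; their lists, oxidative stress and unfolded protein response, averaged 0.582 over 17 and 0.264 over 36, with adjusted p = 0.495 with an estimated correlation for both. The oxidative stress call ended without SD array 1 (0.383, adjusted p = 0.0852) or HFD array 3 (0.443, adjusted p = 0.0629), and the unfolded protein call without HFD array 1 (0.216, adjusted p = 0.0533).

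White adipocyte markers averaged -0.887 over 16, with 3 lower over the list alone and 0 calls (Retn, resistin, -5.71; Nnat -3.08; camera adjusted p = 0.00759; adjusted p = 0.495 with an estimated correlation). Their mean was -0.371 without control SD array 1 (adjusted p = 0.146), -0.371 without the 2 arrays of lowest Ucp1 (0.131) and -0.37 with the muscle score as a covariate (0.217), and the call ended in each. Skeletal muscle markers averaged -5.89 over 24, all negative with 0 calls (camera adjusted p = 4.83e-08; adjusted p = 0.522 with an estimated correlation), or -3.76 without SD array 1 and -9.56 without SD array 2.

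In BAT arrays labelled cKO, HFD gave 0 calls by limma (3920 genes at an unadjusted p under 0.05; lowest adjusted p 0.0665). Cdh9 stood at 1.92, the phospholipid transfer protein gene Pltp at 2.55, Plscr2 at 0.866 and Msn at 1.36, against Myh10 at -1.5, Tet2 at -0.725, Selenbp1 at -1.0 and Prodh at -0.658. The count was 1183 without SD array 1, 2 without HFD array 1, 1 without HFD array 3, 13 after quantile normalization and 8643 with array weights. Diet effects in the 2 genotypes correlated at 0.893 across genes (Spearman 0.744), where 0 of 100 rearrangements were as high and the highest was 0.841. The lowest was -0.896, so rearranged labels also reached a correlation of this size with the opposite sign.

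Cholesterol synthesis genes averaged 1.36 over 18, all positive, with 0 calls and 12 over the list alone (Nsdhl 2.90, Fdps 2.0, Lss 1.79, Insig1 3.26; camera adjusted p = 2.73e-07; adjusted p = 0.553 with an estimated correlation), and 0.881 with the muscle score as a covariate. Proteasome genes averaged 0.783 over 24, all positive, with 0 calls and 17 over the list alone (Psmd14 1.63, Psmc4 1.27; camera adjusted p = 3.65e-08; adjusted p = 0.553 with an estimated correlation). Macrophage markers averaged 1.05 over 25, with 0 calls and 14 over the list alone (Ctss 3.45, Cd68 2.49, C1qb 2.22; camera adjusted p = 2.73e-07; adjusted p = 0.553 with an estimated correlation). Muscle markers averaged -6.53 in the same comparison (camera adjusted p = 9.49e-09; adjusted p = 0.553 with an estimated correlation).

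Genotype gave 0 BAT genes by limma on SD (610 at an unadjusted p under 0.05, where chance gives 856), on HFD (1414), averaged (1495) and in the interaction (649). On SD Rpsa-ps4 (0.645), Zbtb10 (1.22), Tet2 (0.486) and Snx16 (0.991) had the highest statistics and Zfp420 (-0.451), Sec13 (-0.385), Farsb (-0.434) and Eif2b1 (-0.404) the lowest. Zbtb10 and Snx16 lie among the chromosome 3 neighbours. The core clock list passed camera on SD, a call lost with an estimated correlation. It also ended with array weights (0.0112, adjusted p = 0.831) and with the muscle covariate (0.133, adjusted p = 0.108). Without the 2 arrays of lowest Ucp1 the list averaged 0.211 (camera adjusted p = 0.0526). On HFD Rassf9 stood at -2.12 and Tnc, tenascin C, at -0.837, each with an adjusted p of 0.0578 and Tnc with a cKO mean of 4.065, below the filter level of 4.1275, followed by Meox1 (-1.26) and Galnt18 (-0.843), against Acsl4 (0.723), Plekhf1 (0.749), Btla (0.466) and Gldc (0.699, with all control arrays below that level). The HFD count was 16 without control array 3, 1 without cKO array 1, 191 with array weights, 2 with the trended prior and 1 without the 2 arrays of lowest Ucp1. The averaged count was 5 without control HFD array 3 and 1 without control SD array 1, and the interaction 2 without control HFD array 3 and 1 without cKO HFD array 1. Genotype effects on the 2 diets correlated at 0.466 across genes (Spearman 0.348; the highest of 100 rearrangements was 0.465), but at 0.284 without cKO HFD array 3 and at -0.00768 without control SD array 2.

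On HFD, endothelial markers averaged -0.583 over 21 in BAT arrays labelled cKO, with 0 calls and 1 higher and 7 lower over the list alone (Cldn5 -1.47, Pecam1 -1.33, Eng -1.73; camera adjusted p = 0.000101; adjusted p = 0.548 with an estimated correlation). Cell cycle genes averaged -0.402 over 16, with 0 calls and 5 lower over the list alone (Mki67 -1.56, Tpx2 -0.545; camera adjusted p = 1.87e-08; adjusted p = 0.485 with an estimated correlation). Muscle markers averaged 2.16 there (camera adjusted p = 0.00616; adjusted p = 0.86 with an estimated correlation), or 3.94 without cKO array 1 and 0.655 without cKO array 3, which ended the call (adjusted p = 0.523). On SD, cholesterol synthesis genes averaged -0.796 over 18, with 0 calls (camera adjusted p = 1.07e-07; adjusted p = 0.675 with an estimated correlation). That mean was -0.368 without control array 2 and -0.41 with array weights, which ended the call (adjusted p = 0.0945). On HFD the same list averaged 0.398, with 14 of 18 members positive and 0 calls (camera adjusted p = 0.00691; adjusted p = 0.775 with an estimated correlation), and that call ended without control array 1 (0.274, adjusted p = 0.0872). Muscle markers averaged 2.80 on SD (camera adjusted p = 0.000153; adjusted p = 0.682 with an estimated correlation), or -0.865 without control array 2 (adjusted p = 0.0562), 4.93 without control array 1 and 4.34 without control array 3.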

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

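The tests of chromosome 3, muscle and Bmal1 under the other observations were chosen only after the results were seen; the values here come from planned comparisons, and none is explained.

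Features without a single gene symbol, which entered no gene comparison, also gave calls in VMH: 2 lower in arrays labelled cKO on HFD, and 9 averaged over diets (5 higher, 4 lower), with adjustment over 15288 such features.

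For 4 gene lists the genotype effect in VMH differed between the diets by camera on the interaction (HFD minus SD), each with an adjusted p = 0.978 with an estimated correlation. Glucocorticoid responsive genes differed by -0.179 (camera adjusted p = 0.0278), interferon response genes by -0.219 (0.000954), general neuron markers by 0.129 (0.00776), and pituitary, choroid plexus and meninges markers by -0.269 (0.0115). The glucocorticoid call ended without any of control SD arrays 1 and 2, cKO SD array 3, control HFD arrays 2 and 3 and cKO HFD arrays 2 and 3 (-0.0939, -0.174, -0.147, -0.186, -0.178, -0.168 and -0.161, with adjusted p 0.057 to 0.329) and without the filter (-0.106, adjusted p = 0.143), and its mean was -0.269 without control SD array 3. The interferon mean was -0.139 without control SD array 1 and -0.133 without control HFD array 1. The neuron call ended without control HFD array 3 (0.0977, adjusted p = 0.1) or cKO HFD array 3 (0.0927, adjusted p = 0.0581) and after quantile normalization (0.132, adjusted p = 0.151). The pituitary call ended without cKO HFD array 1, where the mean was 0.12 (0.394), without control SD array 2 (-0.234, adjusted p = 0.105), cKO SD array 1 (-0.229, adjusted p = 0.15) or control HFD array 2 (-0.203, adjusted p = 0.0579) and without the filter (0.32, adjusted p = 0.18). With a pseudocount of 16 its mean was 0.0751, although camera still placed it below other genes (adjusted p = 0.039), and its mean was -0.0835, -0.491 and -0.661 without control SD array 1, control SD array 3 and cKO HFD array 2.

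In BAT the same test set 6 lists apart. Heat shock genes differed by 0.408 and fatty acid synthesis genes by 0.706, with camera adjusted p of 0.0199 and 0.0174, and an adjusted p = 0.986 with an estimated correlation for both. The heat shock call ended without control SD array 2 or 3, cKO SD array 1 or 2, control HFD array 2 or cKO HFD array 2 (0.374, 0.385, 0.214, 0.36, 0.338 and 0.0639), and its mean was 0.651 without cKO SD array 3. The fatty acid synthesis call ended without control SD array 2 or 3, cKO SD array 2, control HFD array 1 or cKO HFD array 2 or 3 (0.179, 0.687, 0.0894, 0.568, 0.665 and 0.636), and its mean was 1.25 without control SD array 1. Both calls also ended without the filter (0.408 and 0.673) and with array weights (0.143 and 0.102). Cholesterol synthesis genes differed by 1.19 (6.36e-11), endothelial markers by -0.492 (0.000657) and cell cycle genes by -0.412 (8.29e-08), each with an adjusted p = 0.644 with an estimated correlation. Proteasome genes differed by 0.53 (1.9e-08; adjusted p = 0.701 with an estimated correlation). The cholesterol value was 0.766 without control SD array 2, the proteasome value 0.351 without control HFD array 2 and 0.811 without control HFD array 3, and the endothelial call ended with array weights (-0.182, adjusted p = 0.166). Muscle transcripts varied between the same BAT arrays.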

How the results depend on the processing

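The muscle and neuropeptide covariates, the fit without the 2 arrays of lowest Ucp1, the lists without their 1 called member and the muscle markers without the 8 near a common highest level were chosen after seeing the data; the other alternatives were planned. The cause of each change was not tested, except that fewer arrays or groups in a fit leave fewer degrees of freedom. The number of arrays limits the precision of each value; what signal over background limits was tested only by leaving out the filter.

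All 99 list calls were lost with an estimated correlation (0 lists in each of the 12 comparisons). Fry called 0 lists in 10 comparisons, 4 for diet in BAT controls and 3 for diet in BAT cKO arrays. Quantile normalization gave 1 VMH list for genotype on HFD, 4 for diet in controls, and 80 and 13 BAT genes for diet in controls and cKO. Without the filter, VMH lists numbered 11 (genotype on SD), 4 (diet in controls), 8 (averaged) and 2 (interaction), and the correlation of VMH genotype effects was 0.222. With only the groups compared, VMH gave 10 genes for genotype on SD, 2 lists for genotype on HFD and 0 genes for diet in cKO, and BAT 1 gene for diet in cKO. The trended and robust prior gave 2 BAT genes for genotype on HFD. Changes of the prior, of the pseudocount and of the rule for several features left all VMH gene counts within 1.5 times, as did quantile normalization.

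With array weights, VMH counts were 121 (genotype on HFD), 20 (diet in cKO) and 208 (averaged), with 2 lists averaged; BAT counts were 191 (genotype on HFD), 0 and 8643 (diet in controls and cKO) and 3 (averaged), with 7 lists for genotype on SD. Signs turned for VMH Arntl under diet in cKO (-0.0354); in BAT for Per1 (-0.162), Rorb (-0.0688), Tef (-0.155), the glucocorticoid (-0.111), lymphocyte (-0.107) and extracellular matrix (-0.0848) lists on SD; for Arntl under diet in cKO (-0.324); and averaged for Nr1d2 (-0.03) and fatty acid synthesis (0.0159). The BAT fatty acid synthesis mean on SD shrank to -0.0349, and only camera's direction turned. The VMH pituitary means for diet in cKO and the interaction turned to 0.367 and 0.32 without the filter and to 0.129 and 0.0751 with the pseudocount. Quantile normalization turned the BAT Arntl interaction to 0.0402.

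The labels number arrays 1 to 3 in each group. Same-number correlations of deviations ran from -0.351 to 0.28 in VMH and from -0.772 to 0.39 in BAT. Pairs of different number ran from -0.254 to 0.339 in VMH and from -0.452 to 0.812 in BAT. The numbers therefore gave no sign of a pairing, but these deviations, from means of 3 arrays, cannot exclude one. With the replicate block, BAT diet in controls gave 0 genes, and other gene and list counts stayed within 1.5 times. In VMH it ended the calls of Npas2 (adjusted p = 0.058) and Prex2 (0.133) on SD and of Phyhd1 (0.071), Cyp4f14 (0.103) and Zkscan2 (0.0581) on HFD and Aqp4 (0.0771) averaged, and Olig2 passed on HFD (0.0181). In BAT it ended the calls of the genes named for diet in controls (0.0551 to 0.0963) and of the averaged oxidative phosphorylation list (0.0624), and in VMH that of cholesterol synthesis for diet in cKO (0.0641).

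The muscle covariate gave 0 BAT genes for diet in controls, 7 lists averaged, and oxidative phosphorylation at 0.0132 averaged, the opposite sign. As the muscle score differed between the diets (-6.21), this covariate cannot separate muscle from diet in the diet comparisons. Without the 2 arrays of lowest Ucp1, BAT gave 1 gene for genotype on HFD, 0 for diet in controls and 1 for diet in cKO.

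Leaving out each array, VMH genes ranged from 22 to 51 (genotype on SD), 31 to 39 (on HFD) and 1 to 3 (diet in cKO), and BAT genes from 0 to 16 (genotype on HFD), 0 to 5 (averaged), 0 to 2 (interaction), 0 to 2716 (diet in controls) and 0 to 1183 (diet in cKO). VMH lists ranged from 1 to 11 (genotype on SD, 6 with all arrays), 2 to 6 and 6 to 12 (diet in controls and cKO, 2 and 10), 1 to 9 (averaged, 4) and 2 to 7 (interaction, 4), and BAT lists from 5 to 19 (genotype on SD, 16), 8 to 21 (averaged, 14) and 4 to 11 (interaction, 6). Correlations across genes ranged from 0.217 to 0.358 (VMH genotype), 0.122 to 0.278 (VMH diet) and -0.00768 to 0.514 (BAT genotype). Turned signs appeared for Arntl in VMH diet in cKO (-0.153 to 0.122), BAT genotype on SD (-0.0248 to 0.696) and the BAT interaction (-0.354 to 0.368), for the muscle (-0.865 to 4.93) and skin (-0.0156 to 1.7) lists on SD in BAT, for BAT lymphocytes on SD without control SD array 2 (-0.0056), and for VMH pituitary markers without cKO HFD array 1 (0.181 for diet in cKO, 0.12 for the interaction).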

Other observations

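The tests of muscle, chromosome 3 and Bmal1 in this part were chosen only after the results were seen; the list tests and the splits were planned.

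Among energy metabolism lists of BAT, fatty acid oxidation and lipolysis genes averaged 1.48 ± 0.15 (SE over 35 genes) higher on HFD in controls and 1.24 ± 0.13 in arrays labelled cKO, with 33 of 35 positive in each, 0 calls by limma, and 2 and 0 over the list alone (camera adjusted p = 4.83e-05 and 0.000248; adjusted p = 0.692 and 0.581 with an estimated correlation). Oxidative phosphorylation genes averaged 0.694 and 0.674, with 37 of 39 positive in each (camera adjusted p = 0.000915 and 0.000508; adjusted p = 0.742 and 0.618 with an estimated correlation). With the muscle score as a covariate, fatty acid oxidation averaged 0.577 in controls (adjusted p = 0.0376) and 0.242 in cKO arrays (0.367), and oxidative phosphorylation 0.101 and 0.0159 (0.841 and 0.977), so that all but the first call ended. The muscle score itself differed by -6.21 between the diets, so the covariate also takes up diet. The calls it ended therefore cannot tell muscle from diet. Fatty acid oxidation averaged 0.691 in controls without SD array 1 and 0.729 in cKO arrays without SD array 2. Oxidative phosphorylation averaged 0.27 in controls without SD array 1 (adjusted p = 0.241) and 1.08 without SD array 2, and in cKO arrays 1.12 without SD array 1 and 0.359 without SD array 2.

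In VMH of arrays labelled cKO, extracellular matrix genes averaged -0.302 on HFD over 10 genes, all negative (camera adjusted p = 5.44e-05; adjusted p = 0.502 with an estimated correlation), or -0.157 without HFD array 1. Pituitary, choroid plexus and meninges markers averaged -0.208 there (camera adjusted p = 0.000738), a call also lost with an estimated correlation. Without HFD array 1 their mean was 0.181 and the call ended (adjusted p = 0.161).

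Skeletal muscle transcripts differed by -6.21 on the log2 scale in BAT, HFD minus SD over all arrays, and by -6.24 over the 16 markers left without the 8 whose 2 highest arrays lay within 0.05 of each other, 1 of them at the ceiling. Diet does not account for the spread within groups. The mean signal of the 24 markers was 17.3, 5.71 and 16.1 on control SD arrays 1 to 3. It was 5.77, 9.86 and 12.3 on cKO HFD arrays 1 to 3. Control SD array 1 and cKO SD array 2 had the highest muscle signal (17.3 and 17.1) and the lowest Ucp1 (8.87 and 16.3). This argues against a diet effect inside brown adipocytes as the whole cause on these 2 arrays. Control SD array 3 (16.1) had Ucp1 at the ceiling. Without the 2 arrays of lowest Ucp1 the diet difference was -3.76 in controls and -5.9 in cKO arrays. Over those other arrays a diet effect inside brown adipocytes as its whole cause stays open. Over all arrays the SD within groups was 0.608 of the diet difference (0.561 over the 16). Only 1 SD array lay below the highest HFD array, while all 6 HFD arrays lay above the lowest SD array. The 24 markers varied together within groups, with a median pairwise correlation of 0.9667 (0.9771 over the 16), which is consistent with muscle tissue in the samples, a hypothesis that the dissection notes do not settle. With the muscle score as a covariate, macrophage markers averaged 1.41 on HFD in controls; without it their mean was 1.24, with an adjusted p = 0.495 with an estimated correlation.

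The chromosome 3 neighbours from Pex2 to Snx16 stood higher in the arrays labelled cKO in VMH. The genes chosen in VMH had a mean statistic in BAT at percentile 99.99 of 16514 windows, which argues against loss of Bmal1 in Gfap-expressing VMH cells as the whole cause. A DNA difference at the locus carried by these mice may account for it, of a kind not settled here: the median was 0.461 in BAT for the genes chosen in VMH (quartiles 0.21 to 0.757) and 0.75 in VMH for those chosen in BAT (0.633 to 0.8). Probes that match 1 genotype's DNA less well stay open, as the interquartile range was 0.2377.

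Bmal1 was not lower in the arrays labelled cKO. Single arrays with a wrong genotype label are argued against, since 0 of the 24 arrays lay on the other genotype's side of the chromosome 3 genes chosen in the other tissue. The feature may measure transcript parts that the deletion leaves, but the deleted exon is not given in the labels. The VMH interval (lower bound 0.133) cannot test this. Only an interval below 0 would have counted against it, and Bmal1 was already known not to be lower. Bulk samples also keep the transcripts of cells that do not express Gfap. Of 9 BMAL1 targets (Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per1, Per2, Per3, Usp2) 7 had negative differences in VMH, with a mean of -0.08839 (exact permutation p = 0.275, where 0.005 is the smallest possible), so lower BMAL1 activity cannot be told apart from none with 9 genes and these arrays.

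For the two-group comparisons each 3 against 3 makes 10 splits, too few for a share under 0.05. In VMH the real and highest other counts were 44 and 1 (genotype on SD; 1 split as large), 49 and 0 (genotype on HFD; 1), 0 and 1 (diet in controls; 10), and 1 and 0 (diet in cKO; 1). In BAT they were 0 and 2888 (genotype on SD; 10), 0 and 0 (genotype on HFD; 10), 132 and 3 (diet in controls; 1), and 0 and 0 (diet in cKO; 10). For the averaged VMH genotype effect, 100 of the 200 possible splits were drawn, and 1, the real one with 107 genes, gave as many, while the highest other gave 1. With the real split among the 100 drawn, this makes chance in the grouping of these arrays unlikely but does not exclude it. Nor does it exclude chance differences between animals if arrays of a group share one, which the labels do not settle. For the interactions and the averaged BAT effect the real count was 0, so all 100 splits gave at least as many by construction and nothing is read from them. The highest other was 107 in VMH, from the split that exchanges the genotypes on HFD and so turns the interaction into the averaged genotype effect, and 1237 in both BAT comparisons. The splits of 2888 and 1237 genes point to a structure of the BAT arrays other than their groups. The first principal component of BAT, with 72.2% of the variance, ran with the muscle signal. Control SD array 1 (muscle 17.3) and cKO SD array 2 (17.1) lay at -102 and -113 on it, and control SD array 2 (5.71) at 55.3. Whether these splits follow that component was not tested.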
